A study of Rattus norvegicus with 30 samples.

How the data were processed

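RNA was measured in hypothalamus from male Sprague-Dawley rats, an outbred laboratory strain, aged about 2 months. The animals had received either a sham procedure or a fluid percussion injury, a model of traumatic brain injury (TBI) in which a fluid pulse strikes the exposed dura, and were killed 1 week later, directly after a glucose tolerance test. Per the labels' protocols, total RNA libraries were made with a strand-specific kit that removes ribosomal RNA, and were sequenced as read pairs. The 30 libraries come from 10 animals, each run on 3 lanes. The titles number the animals 1, 2, 3, 5 and 6 in one group and 1 to 5 in the other. The first group is labelled by its treatment, water, and was taken as the sham group because the series' design names sham and TBI rats with 5 animals in each. This mapping rests on that design text.

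Reads were aligned with HISAT to rn6 and quantified with StringTie, per the submitters' processing notes. Their versions are not given in the sources used here. Each library has one deposited StringTie abundance table. It lists 17337 annotated genes on 17764 to 17786 rows, and between 49716 and 108948 loci that StringTie assembled from the reads and that carry no gene name. The deposited coverage column (unit signal) is the mean read depth per base of a gene or locus. The deposited FPKM column is a value scaled for gene length and fragments mapped, as the authors' software computed it. The deposited TPM column was taken as a signal, because its values do not have the scale of TPM: the assembled loci alone sum to 1000000 in each library, and the annotated rows come on top with another 413727 to 590726. Assembled loci therefore cover annotated genes a second time, and values of annotated genes are comparable between libraries only after scaling. The test planned for TPM was kept, since it works on the log scale. Within a library the TPM column was a constant multiple of the FPKM column to within 1e-05.

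Annotated rows of one gene were summed, assembled loci were left out of the gene tests, and an animal's value was the mean over its 3 lanes, which were taken as technical runs of one library; the titles name the lane, and separate libraries per lane are not excluded. Values were divided by a size factor per animal, the median over 13315 genes above 0 in every animal of the ratio to the geometric mean. Size factors ran from 0.908 to 1.15. The 11573 genes with a mean scaled value of at least 1 were tested. The rn6 annotation of the files gave names and coordinates. A RefSeq table of another rat assembly, GRCr8, was used for symbols only and matched 11428 of the tested symbols or their synonyms (98.7%). An annotated row can hold part of a gene's signal: in 68.6% of tested genes the row held at least 50 percent of the assembled signal on the same strand at its place. In 275 tested genes the symbol stood at several places, so that reads could be split between copies.

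Genes were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes (trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, TBI over sham, and understate the change of low genes. The 30 gene lists were fixed before the data were examined. The 29 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with the rotation test fry. The list of mitochondrially encoded genes had 0 tested members and was not analysed here. A list score is the mean over members of the log2 deviation from the 10-animal mean. List medians were set against 10000 random lists matched in 20 bins of mean expression. Those lists draw unrelated genes, so a list of correlated genes reaches an extreme percentile more easily. Library measures and list scores were compared with exact two-sided permutation tests over all 252 assignments of 5 animals, whose smallest p is 0.00794. The distance between groups was tested one-sided over the 126 distinct splits. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

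The rule for named genes gave, per direction, 10 genes with no overlap between groups and an adjusted p under 0.05. Where fewer passed, the places went to the genes with the smallest p in that direction, leaving out uncharacterised, Mir and pseudogene-like symbols. The rule added 11 genes fixed in advance (Pomc, Agrp, Npy, Crh, Trh, Lepr, Insr, Igf1r, Bdnf, Gfap, Aif1) and, for each list described, the 2 to 4 members with the smallest p. Genes named outside it are said to be chosen after their values were seen.

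The tables hold no read counts, so depth per sample is unknown. The ratio of coverage to FPKM, which follows relative depth, lay between 1.34 and 1.81 over the libraries. Lanes of one animal differed by a median SD of 0.101 on the log2 scale and animals of one group by 0.140, and lane error made up a median of 17.4% of the variance between animals, if the lanes hold one library. The mitochondrial share of the assembled signal differed between lanes of some animals, up to 3.54-fold in TBI replicate 4 (0.334% to 1.18%). Precision is set by 5 animals per group. The gene test was tested on simulated data with the means and spreads of the 11573 genes, 5 animals against 5, and 200 changed genes. It recovered 24% of 50 genes changed 1.25-fold, 92% of 50 changed 1.5-fold, 86% of 50 changed 2-fold and 98% of 50 changed 3-fold, with 6 false calls, and made 0 calls where no gene was changed. The simulated genes varied independently, which genes of one tissue sample do not.

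Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5, values as deposited, annotated genes rescaled to a common total, quantile normalization, FPKM, single lanes, 30 lane libraries with the animal as a random block, the highest row per gene, non-robust moderation, array weights, the animal number as a block, and leaving out each animal. Alternatives chosen after seeing the data were leaving out sham replicate 6 with TBI replicate 4, leaving out sham replicates 1 and 3, the number of assembled loci as a covariate, cyclic loess, and only genes whose row held at least 50 percent of the assembled signal.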

Results

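Hypothalamic RNA of 5 sham and 5 TBI rats was compared 1 week after injury. The hypothalamus controls feeding, glucose balance and the pituitary, and the comparison asks how its transcriptome differed after brain trauma. Each animal's value is the mean of 3 lanes, scaled by its size factor, and is called the scaled value. Read depth is unknown, because the tables hold no counts. Coverage per FPKM unit, which follows relative depth, was 1.48 ± 0.154 in sham and 1.51 ± 0.0525 in TBI (SD, n = 5 each; exact permutation p = 0.762, adjusted p = 0.841). Without sham replicate 6, whose value was 1.75, the groups did not overlap: the other sham animals lay between 1.37 and 1.46 and TBI animals between 1.47 and 1.597 (adjusted p = 0.0317, exact permutation).

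No single gene passed the threshold. Of 11573 genes, 0 had an adjusted p under 0.05 (limma), and 1077 had an unadjusted p under 0.05, where 578.65 would be expected by chance. Of these, 550 were higher and 527 lower in TBI. The groups did not overlap in 280 genes (132 higher, 148 lower in TBI), which is 2.42% of genes against 0.794% expected per gene by chance. Genes of one sample vary together, so neither expected figure gives the spread of such a count. Of 100 splits of the animals, 13, the real one among them, gave at least 1077 genes. The 280 genes were not set beside other splits. The balance of higher and lower genes depended on the scaling. With the values as deposited, 32 were higher and 894 lower at an unadjusted p under 0.05. The median of all tested genes was then -0.07 on the log2 scale. With annotated genes rescaled to a common total that median was -0.22, and 1345 genes passed. Without sham replicate 1, 14 genes passed, all with lower values in TBI. The smallest adjusted p, 0.0649, belonged to LOC688452, an uncharacterised locus (rn6 chromosome 1, 59704998 to 59715763), named after its value was seen. Its scaled value was 5.601 ± 0.360 in sham and 3.31 ± 0.310 in TBI (SD, n = 5 each).

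Among the genes with the smallest p that had higher values in TBI, 3 encode proteins of the large ribosomal subunit, Rpl9, Rpl35 and Rpl32. The scaled value of Rpl35 (rn6 chromosome 3, 23294813 to 23297774, minus strand) was 465 ± 20.1 in sham and 562 ± 16.0 in TBI, a log2 fold change of 0.28 ± 0.046 (SE, limma adjusted p = 0.115). Rpl9 had a log2 fold change of 0.34 and stood at 3 places in the annotation, so its reads can be shared with copies. Fads2, a desaturase of polyunsaturated fatty acid synthesis, was 70.6 ± 3.10 in sham and 82.8 ± 2.83 in TBI (log2 fold change 0.23, adjusted p = 0.208). Atpif1, the inhibitor of the mitochondrial ATP synthase, had a log2 fold change of 0.22 (adjusted p = 0.213). Tmsbl1, Lyrm1 and Lix1 had log2 fold changes of 0.35, 0.35 and 0.28. Bc1, a short noncoding RNA of neuronal dendrites (rn6 chromosome 1, 218075359 to 218075511), was 8730 ± 1400 in sham and 13188 ± 2306 in TBI (log2 fold change 0.59, adjusted p = 0.222). Snap25, a synaptic vesicle fusion protein, had a log2 fold change of 0.39 (adjusted p = 0.224), but its annotated row held 1.39% of the assembled signal at its place.

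Among the genes with lower values in TBI, Pabpn1, a nuclear poly(A)-binding protein (rn6 chromosome 15, 33555640 to 33560251), was 41.5 ± 4.13 in sham and 29.0 ± 1.73 in TBI, a log2 fold change of -0.50 ± 0.073 (SE, limma adjusted p = 0.109). Akap8l, a nuclear anchoring protein, was 40.5 ± 5.85 in sham and 26.5 ± 1.04 in TBI (log2 fold change -0.58, adjusted p = 0.115). Both passed with array weights, together with LOC688452, and both were among the genes that passed without sham replicate 1. That animal had the lowest sham value of Pabpn1 (34.6) and of Akap8l (30.3), so leaving it out widens both differences. Crtc2, a coactivator of CREB, had a log2 fold change of -0.45, C1ql2, a secreted synaptic organiser, -0.58, and Col11a2, a fibrillar collagen chain, -0.68. The others were Zfp692 at -0.69, Vwa5b2 at -0.48, Gigyf1 at -0.39, Mzf1 at -0.48 and Nrbp2 at -0.52, with adjusted p between 0.115 and 0.143. The annotated rows of Vwa5b2, Crtc2, Gigyf1 and Col11a2 held 22.6%, 31.1%, 36.3% and 37.0% of the assembled signal at their places.

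Camera called 9 of 29 lists, 5 higher and 4 lower. The list of nuclear-encoded oxidative phosphorylation genes was higher in TBI: 39 of 39 members had higher values, with a median log2 fold change of 0.12 (adjusted p = 1.6e-11; adjusted p = 0.699 with an estimated correlation). Of its members 0 passed over all genes, and 3 passed when adjusted over the list alone: Cox7a2, a cytochrome c oxidase subunit (log2 fold change 0.33), and the complex I subunits Ndufs3 (0.25) and Ndufb5 (0.26). Of 50 cytosolic ribosomal protein genes 47 had higher values (median 0.09, adjusted p = 4.9e-10; adjusted p = 0.699 with an estimated correlation), and Rpl35, Rpl32 and Rps7 passed when adjusted over the list alone. Glycolysis and glucose transport genes had higher values in 16 of 19 members (median 0.05, adjusted p = 0.0272; adjusted p = 0.699 with an estimated correlation), among them Pkm, Pgk1 and Pfkm with log2 fold changes of 0.16, 0.17 and 0.13. That call ended without sham replicate 3 or 5 or TBI replicate 2, 4 or 5 (adjusted p from 0.0523 to 0.135). Among lists matched on abundance the oxidative phosphorylation median stood at the 99.99th percentile, the ribosomal median at the 94.16th and the glycolysis median at the 10.06th, below the matched median of 0.08. After cyclic loess the medians were 0.05, 0.007 and -0.02 (adjusted p = 0.000352, 0.196 and 0.628), and after quantile normalization 0.05, 0.01 and -0.02, so that glycolysis turned under both and the ribosomal call ended under both. With the number of assembled loci as a covariate they were 0.05, 0.03 and 0.01 (adjusted p = 0.00308, 0.0174 and 0.528).

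Markers of neurons and of myelin were higher as lists. Of 18 neuron markers 17 had higher values in TBI (median 0.13, adjusted p = 8.6e-05; adjusted p = 0.699 with an estimated correlation). Snap25 and Nefh, the heavy neurofilament chain, passed when adjusted over the list alone, with log2 fold changes of 0.39 and 0.42. Of 19 oligodendrocyte and myelin markers 15 had higher values (median 0.14, adjusted p = 0.0218; adjusted p = 0.704 with an estimated correlation), and Mobp and Mal, both myelin proteins, passed when adjusted over the list alone (0.35 and 0.39). The myelin call ended without sham replicate 1 (adjusted p = 0.701) or TBI replicate 4 (0.0735). The neuron and myelin medians stood at the 99.91st and 100th percentile of lists matched on abundance. Both calls ended after cyclic loess, with medians of 0.04 and 0.08 (adjusted p = 0.101 and 0.172), and after quantile normalization, with medians of 0.06 and 0.09. With the number of assembled loci as a covariate the myelin call ended (median 0.05, adjusted p = 0.878), and without sham replicates 1 and 3 its test pointed down (adjusted p = 0.375).

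Inflammatory, meningeal and pituitary genes were lower as lists. Of 21 tested cytokine and innate immune genes 17 had lower values in TBI (median -0.20, camera adjusted p = 0.0185, or 0.699 with an estimated correlation). The list has 31 members, and those with a mean scaled value under 1, among them Il1b, Il6, Tnf and Ccl2, were not tested. The result does not cover them. Members with the smallest p were the interferon-induced genes Isg15, at 7.63 ± 3.16 in sham and 3.92 ± 0.721 in TBI, and Ifit3 (log2 fold changes -0.75 and -0.44). All 13 tested reactive astrocyte genes had lower values (median -0.20, adjusted p = 0.0272; adjusted p = 0.699 with an estimated correlation), with Tm4sf1 at -0.22 and Emp1 at -0.41. Gfap, the astrocyte intermediate filament, was 267 ± 61.2 in sham and 247 ± 75.3 in TBI (adjusted p = 0.863). All 15 fibroblast and meningeal markers had lower values (median -0.42, adjusted p = 0.0272; adjusted p = 0.741 with an estimated correlation), led by Col1a1 (-0.60) and Dcn (-0.58). Reactive astrocyte and fibroblast scores were both highest in sham replicate 5 (0.47 and 1.07). Both were lowest in sham replicate 2 (-0.36 and -1.51) and TBI replicate 2 (-0.42 and -1.25). Whether these lists changed apart from each other was not tested. All 8 tested pituitary hormone and lineage genes had lower values (median -0.43, adjusted p = 0.0272; adjusted p = 0.699 with an estimated correlation), among them Lhb (-0.29) and Nr5a1 (-0.56). The pituitary score was 0.77 to 1.63 in sham replicates 1, 3 and 5 and TBI replicate 5, and at most -0.53 in the other animals. In these 4 lists 0 members passed when adjusted over the list alone, and leaving out sham replicate 5 ended each call (adjusted p = 0.317, 0.317, 0.362 and 0.0885), as did leaving out TBI replicate 4 (0.0735, 0.135, 0.102 and 0.213). The reactive astrocyte call also ended without sham replicate 1 (0.0518) or 3 (0.0651) or TBI replicate 2 (0.137), the fibroblast call without sham replicate 1 (0.132), 3 (0.0797) or 6 (0.0735) or TBI replicate 2 (0.325), and the pituitary call without sham replicate 1 (0.152) or 3 (0.122). With the number of assembled loci as a covariate all 4 calls ended: the medians of the cytokine, reactive astrocyte, fibroblast and pituitary lists were -0.12, -0.05, -0.08 and -0.13 (adjusted p = 0.0797, 0.528, 0.927 and 0.878). After cyclic loess they were -0.14, -0.18, -0.38 and -0.39, and these calls ended too (adjusted p = 0.149, 0.169, 0.101 and 0.149).

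**Figure D1:**
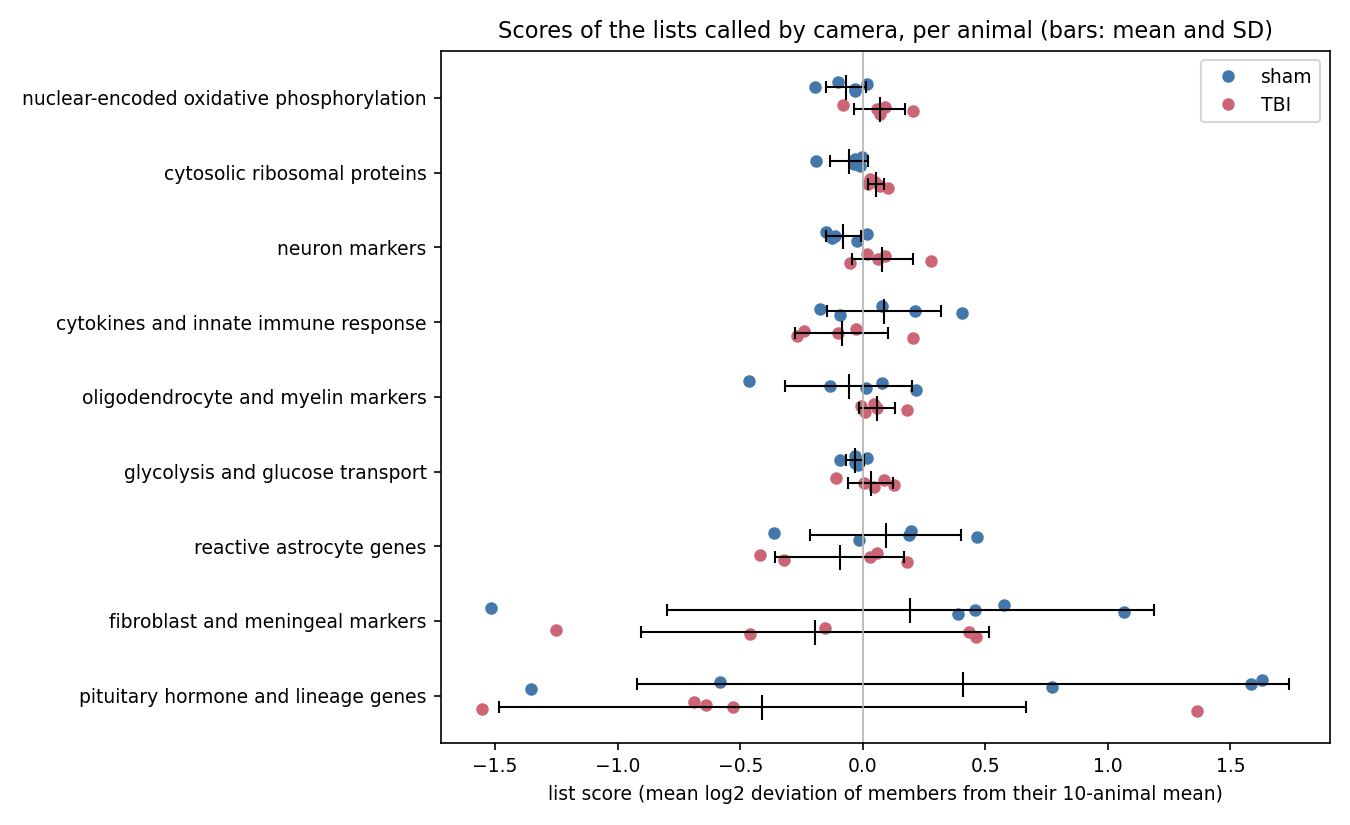
Scores of the 9 lists called by camera, in log2 units (mean deviation of members from their 10-animal mean), with 1 point per animal in sham (blue) and TBI (red) and black bars for mean and SD. The oxidative phosphorylation score had a mean of -0.07 in sham and 0.07 in TBI with overlapping ranges, and sham replicate 2 lay at -1.51 in the fibroblast and meningeal score.

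Scores were also compared between animals with exact permutation tests over the 29 lists, chosen after the data were seen. The ribosomal protein score differed by 0.11 (p = 0.00794, the smallest possible; adjusted p = 0.230), and was above the sham mean in 5 of 5 TBI animals. The oxidative phosphorylation and neuron scores differed by 0.14 and 0.16 (p = 0.0476 and 0.0317 by the same exact permutation; adjusted p = 0.460 for both). None of the 29 passed the adjustment. A list that is alone at the smallest possible exact permutation p has an adjusted p of 0.230. No single list could therefore pass, however far apart the groups lay.

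Peptides that control feeding and hormone release were not called as a list. The test looks for a shared direction, so opposed changes of members would not show in it. Of 24 feeding and endocrine neuropeptides 14 had higher and 10 lower values (camera adjusted p = 0.894), with the smallest p for Nts (log2 fold change 0.41) and Gnrh1 (0.85). Pomc, precursor of melanocortin peptides that reduce feeding, was 43.7 ± 20.6 in sham and 35.8 ± 25.1 in TBI (adjusted p = 0.815). Agrp, which promotes feeding, was 16.4 ± 10.3 and 13.8 ± 9.14 (adjusted p = 0.921). The SE of the log2 fold change was 0.76 for Pomc and 0.90 for Agrp, so large changes of these genes are not excluded. Npy was 73.9 ± 30.8 and 67.6 ± 29.6 and stood at 3 places in the annotation. Crh was 3.24 ± 1.87 and 3.80 ± 2.65, and Trh was 77.2 ± 37.9 and 83.1 ± 23.6 (all SD, n = 5 each). Of 26 genes of metabolic hormone receptors and signalling 17 had lower values (median -0.04, adjusted p = 0.182), with Crhr2 at -0.36 and Fgfr1 at -0.20. The list was called, as lower, without TBI replicate 1 (0.0347). The receptors Lepr, Insr and Igf1r had log2 fold changes of -0.14, -0.07 and -0.11 with adjusted p between 0.821 and 0.850. Their annotated rows held 12.8%, 34.3% and 34.9% of the assembled signal at their places, and that of Agrp 16.2%. Bdnf, a growth factor of synaptic plasticity, had 3.70 ± 0.895 in sham and 3.90 ± 1.04 in TBI (adjusted p = 0.933).

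Stress, clock and lipid lists were not called. Adjusted p was 0.0732 for cholesterol and lipid metabolism (median 0.08, Msmo1 0.16 and Idi1 0.18), 0.345 for glucocorticoid-responsive genes, 0.478 for circadian clock genes, 0.0999 for immediate early genes, 0.345 for the unfolded protein and heat shock response and 0.216 for synaptic plasticity. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was 44.2 ± 2.57 in sham and 55.8 ± 6.61 in TBI (log2 fold change 0.33) and passed when adjusted over the list alone (adjusted p = 0.0177), not over all genes (0.237). Per1 had the next smallest p in that list, with a log2 fold change of -0.21. Cholesterol and lipid genes were called without sham replicate 3 (adjusted p = 0.00294), as was synaptic plasticity (0.0474). Immediate early genes were called without sham replicate 1, 2 or 3 or TBI replicate 2 (adjusted p from 0.0249 to 0.0457). With the number of assembled loci as a covariate, cholesterol and lipid genes (adjusted p = 0.00118), synaptic plasticity (0.00932) and glucocorticoid-responsive genes (0.0481) were called as higher and immediate early genes (0.00118) as lower. Without sham replicates 1 and 3 the cholesterol (0.00289), synaptic (0.00528) and immediate early lists (0.00150) were called in the same directions. Cholesterol genes were also called with no filter (0.0412), array weights (0.0259) and lane libraries with the animal as a random block (0.0173), and immediate early genes in lane 2 (0.0320) and with array weights (0.0342). The random block enters several lanes per animal and adds no animals, so its p can be too small. The clock median was 0.005 while its mean was -0.04 and its test pointed down.

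Of the cell type and regional lists not called, adjusted p was 0.0732 for astrocyte, 0.324 for oligodendrocyte precursor, 0.497 for microglia, 0.912 for endothelial, 0.0844 for mural, 0.497 for ependymal and ciliated, 0.497 for tanycyte and 0.0732 for choroid plexus markers. It was 0.186 for thalamus, 0.623 for cortex and hippocampus and 0.680 for striatum markers, and 0.916 for red blood cell genes. All 15 thalamus markers had higher values in TBI (median 0.21), with the smallest p for Adarb1 (0.34) and Slitrk6 (0.18). Several of these lists were called when 1 animal was left out. Astrocyte markers were called, as higher, without sham replicate 1, 2 or 3 or TBI replicate 3 or 4 (adjusted p from 0.0339 to 0.0496). Thalamus markers were called, as higher, without sham replicate 6 (0.00218) or TBI replicate 1 (0.0262) or 3 (0.0427). Mural markers were called, as lower, without sham replicate 2 (0.00764) or TBI replicate 1 (0.0347) or 3 (0.0250), choroid plexus markers, as lower, without sham replicate 2 (0.00902), and microglia markers, as lower, without TBI replicate 5 (0.0143). Astrocyte markers were also called with the loci covariate (0.0136), without sham replicates 1 and 3 (0.00528), with no filter (0.0412), in lane 4 (0.0418), with array weights (0.0333) and with the animal as a random block (0.00669). Mural markers were called with array weights (0.0278) and the random block (0.0297), thalamus markers with the random block (0.0333), and choroid plexus markers among genes whose row held at least 50 percent of the assembled signal (0.0216). For these random-block calls too, p can be too small, because several lanes per animal were entered. Aif1, a microglial calcium-binding protein, was 16.8 ± 2.67 in sham and 15.8 ± 1.99 in TBI (adjusted p = 0.840). The cortex and hippocampus median was -0.003 with a mean of 0.02 and a test pointing down.

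Animals differed within groups in genes of particular hypothalamic and pituitary regions. Cga, the shared subunit of glycoprotein hormones, was 448, 346 and 98.6 in sham replicates 1, 3 and 5 and 391 in TBI replicate 5, and at most 5.02 in the other 6 animals. Pomc and Agrp were lowest in sham replicate 6 (16.2 and 1.58) and TBI replicate 4 (2.93 and 0.536), where Oxt, which encodes oxytocin, was 1170 and 1165. Cga, Oxt and the 2 further genes plotted with them, Tshb and Avp, were chosen after their values were seen. Without those 2 animals 0 genes passed and 6 lists were called.

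**Figure D2:**
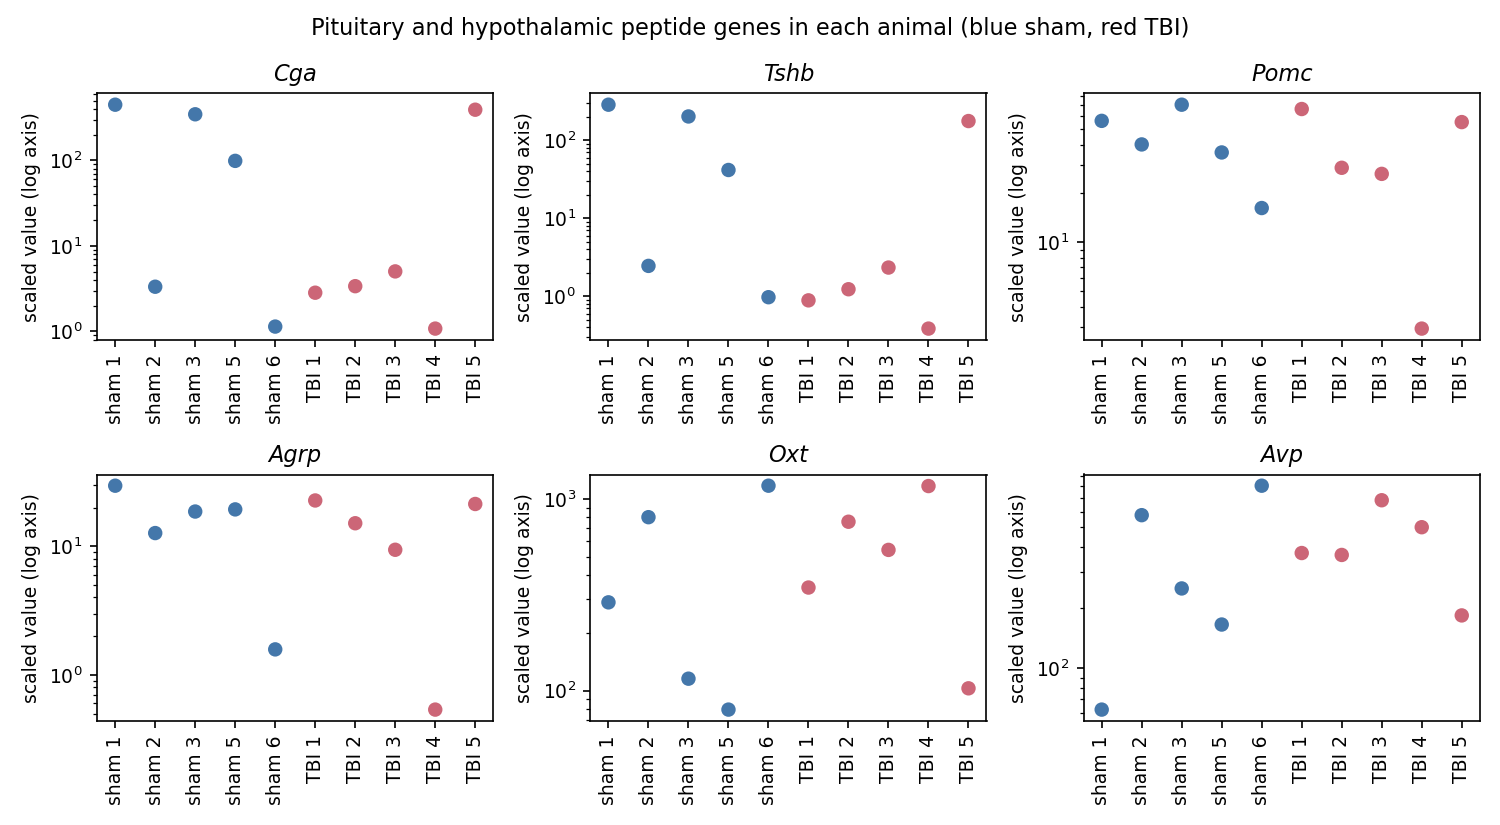
Scaled values (log axes) of Cga, Tshb, Pomc, Agrp, Oxt and Avp in each of the 5 sham (blue) and 5 TBI (red) animals, 1 point per animal. Cga was above 98 in sham replicates 1, 3 and 5 and TBI replicate 5 and at most 5.02 elsewhere.

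The share of annotated signal in the 10 most abundant genes was higher in TBI, at 36.8% ± 3.73 against 27.5% ± 3.31 in sham (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0476). It was above the highest sham value in 5 of 5 TBI animals. Leaving out sham replicate 3 or 5 or TBI replicate 2, 3 or 4 ended that call, with adjusted p of 0.0952, or 0.0714 without sham replicate 5 (exact permutation). Every TBI value lay above every sham value, so the groups stay apart whichever animal is left out. With fewer animals the permutation p moves in coarse steps, so these ended calls do not show that the difference rests on those animals. Much of this share lay in LOC102723236, chosen after its values were seen. Its scaled value was 63590 to 113900 in sham and 118700 to 205300 in TBI. Annotated rows summed to 413727 to 590726 per library before scaling. The share and this locus are therefore not separate results. Under rescaling to a common total, a higher value of this locus lowers all other genes. Annotated genes at 1 or more, counted on the deposited values before scaling, numbered 11622 ± 120 in sham and 11400 ± 136 in TBI (exact permutation p = 0.0317, adjusted p = 0.0635). Assembled loci numbered 72239 ± 20350 in sham and 56213 ± 5867 in TBI (exact permutation p = 0.0952, adjusted p = 0.143). They held 66.7% ± 2.28 and 64.3% ± 0.904 of the whole column (p = 0.0238 by exact permutation, adjusted p = 0.0635). The assembled part of the column has a fixed total, so this percent follows from the annotated sum alone. It does not show that loci held less signal. That sum includes LOC102723236, so the percent and the locus are not separate results either. The assembled locus on the mitochondrial chromosome held 0.521% ± 0.243 and 0.549% ± 0.164 of the assembled signal (exact permutation p = 0.841).

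Fold change ran with abundance. The median log2 fold change was -0.08 in the first of 5 equal bins of genes by abundance, the least abundant, and 0.07 in the last, and 31.4% and 78.5% of genes in them had higher values in TBI. Whole profiles did not separate by group: the mean correlation between animals was 0.982 both between and within groups, and 50 of 126 splits gave as large a difference (one-sided permutation p = 0.397).

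**Figure D3:**
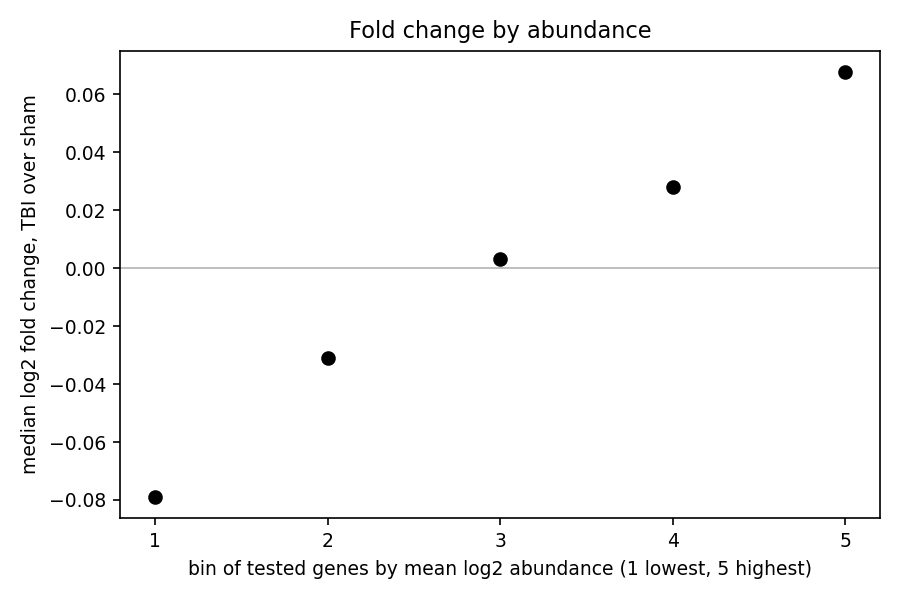
Median log2 fold change (TBI over sham) of the tested genes in 5 equal bins of mean log2 abundance, lowest to highest, 1 point per bin. The medians run from -0.08 to 0.07.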

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

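Bounds for all tests weighed in this part, the counts of splits included, were set after the values had been seen. An animal far from the others of its group was found in 8 of 132 groups of 5 tested, where chance gives about 6.60. Coverage per FPKM unit was 1.75 in sham replicate 6 against 1.37 to 1.46 in the other sham animals. The ribosomal protein score was -0.19 in sham replicate 3 against -0.04 to -0.002. Sham replicate 2 had a fibroblast and meningeal score of -1.51 against 0.39 to 1.07, and a choroid plexus score of -0.46 against 0.13 to 0.37. Bc1 was 11141 in sham replicate 6 against 7856 to 8777. Akap8l was 30.3 in sham replicate 1 against 41.2 to 45.0. In TBI replicate 4, Vwa5b2 was 6.0 against 6.79 to 6.95 and Crtc2 was 3.35 against 4.07 to 4.25.

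The real split of the 10 animals was set beside 99 others. Counting the real one, 54 of 100 splits called at least its 9 lists, and the highest other called 17. At an unadjusted p under 0.05, 13 of 100 splits, the real one among them, gave at least 1077 genes, with 1845 the highest of the others. Chance cannot be excluded for these counts. For genes past the adjusted threshold the comparison decides nothing, since the real count is 0 and so all 100 splits reach it. The highest other gave 108 such genes and the next 6, and 8 of the 99 gave any. The split with 108 set sham replicates 1, 2 and 3 with TBI replicates 1 and 3 against the rest. It could reflect a structure of the samples, which was not tested.

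The higher values of oxidative phosphorylation and ribosomal protein genes were weighed against the trend of fold change with abundance. The ribosomal median stood at the 94.16th percentile of lists matched on abundance, within their central range, so the trend could account for it. The oxidative phosphorylation median stood at the 99.99th percentile, above unrelated genes of like abundance. Members of this list, however, had an estimated correlation of 0.59. The thalamus median reached the 100th percentile in a list that camera did not call (adjusted p = 0.186). The percentile therefore cannot decide whether the trend accounts for the oxidative phosphorylation list. After cyclic loess its call held (camera at the preset correlation, adjusted p = 0.000352) with a median of 0.05 in place of 0.12. With the number of assembled loci as a covariate its median was 0.0482 (adjusted p = 0.00308), so a call remained but most of the size was lost. More background in sham libraries and an effect of injury cannot be told apart for this list, because the number of loci and the group overlap over 10 animals, and its call is absent with an estimated correlation.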

How the results depend on the processing

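Alternatives chosen after seeing the data are leaving out sham 6 and TBI 4 or sham 1 and 3, the loci covariate, cyclic loess and the restriction by row share. Genes passing, 0 as reported, numbered 1345 with annotated genes rescaled to a common total (1 higher, 1344 lower; 5296 at an unadjusted p under 0.05, with all genes shifted by -0.22), 178 with 30 lane libraries and the animal as a random block, 3 with array weights and 4 without sham 1 and 3; it was 0 under the other alternatives. Leaving out single animals gave 0 to 14 genes, with 14 without sham replicate 1, and 729 to 1376 at an unadjusted p under 0.05. Lists called, 9 as reported, numbered 4 with a mean of at least 5, 5 as deposited, 1 with quantile normalization, 1 with cyclic loess, 0 with an estimated correlation and 0 with fry, and 4 to 13 leaving out single animals (4 without sham replicate 5 or TBI replicate 4). Library measures passing, 1 as reported, numbered 2 in lane 2 and 0 with group medians, and 0 to 3 leaving out single animals. The distance p ran from 0.135 to 0.889. The 178 genes of the random block are not read as gains. That setting enters 30 lane libraries, several per animal, and adds no animals. Where lanes of an animal correlate more closely in a gene than the block assumes, its p is too small. How many of the 178 rest on this was not tested. Apart from rescaling, which subtracts one factor per animal, and lists tested with fewer genes or animals, the cause was not tested.

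Directions turned mostly in lists not called as reported and in genes without a call, and the cause was not tested. The direction of a list is that of camera, which works on moderated t. Of 954 list values under alternatives 738 kept direction and side of the threshold, 92 lost a call, 51 gained one and 73 turned. Of 947 values of named genes 877 kept both, 36 gained a call and 34 turned, 6 of them through a shift of all genes. Some of the 92 lost list calls fell under planned settings (camera adjusted p). Rescaling to a common total ended the oxidative phosphorylation (0.248) and ribosomal (0.402) calls. Lane 3 alone ended the cytokine (0.0673), reactive astrocyte (0.0595) and fibroblast (0.0523) calls, and lane 4 the pituitary call (0.113). Array weights ended the pituitary (0.144) and oligodendrocyte (0.154) calls, and no filter the fibroblast (0.0751) and pituitary (0.0573) calls. With annotated genes rescaled to a common total, the direction given by camera turned at adjusted p of 0.0609 (fibroblast, and cortex and hippocampus), 0.176 (tanycyte), 0.218 (glycolysis), 0.356 (choroid plexus), 0.402 (reactive astrocyte, immediate early, mural, ependymal, pituitary), 0.550 (endothelial), 0.602 (metabolic receptors), 0.859 (cytokines) and 0.998 (unfolded protein, microglia), and log2 fold changes fell below 0 for Fads2 (-0.0143), Atpif1 (-0.0254), Crh (-0.139), Trh (-0.0626) and Bdnf (-0.157). As deposited, endothelial (adjusted p = 0.841) and cortex (0.875) lists turned, and Bdnf fell to -0.0170. These 2 settings shift all genes, by medians of -0.22 and -0.07, so the 6 gene values follow from the shift and say nothing about these genes. The same holds for the lists: in 15 of these 17 turns the list median stayed on its side of all genes, and only cortex, near 0, changed side under both. The 6 list calls gained under these settings are not read as gains either. Under other settings 56 list values turned, and among the 9 called lists only glycolysis and oligodendrocyte did. Quantile normalization turned feeding, glycolysis and synaptic lists (all 0.955), unfolded protein (0.860) and endothelial (0.882). No filter turned cortex (0.971), and a mean of at least 5 turned feeding (0.669), striatum (0.881) and the distance between groups (p = 0.413). Lane 2 turned Bdnf (-0.223), lane 3 Crh (-0.0064) and the mitochondrial share (adjusted p = 0.571), lane 4 endothelial (0.596) and striatum (0.965) lists and Aif1 (0.0076), array weights tanycyte (0.934) and Agrp (0.0260), and fry endothelial (0.974). Without sham 6 and TBI 4, endothelial (0.936), ependymal (0.9998) and striatum (0.857) lists turned. Without sham 1 and 3, circadian (0.609), oligodendrocyte and tanycyte (both 0.375) and cortex (0.716) lists turned, with Agrp (0.248), Npy (0.111), Crh (-0.139), Trh (-0.126), Insr (0.0289) and Igf1r (0.156). The loci covariate turned circadian and thalamus (both 0.927), tanycyte (0.878) and cortex (0.961) lists, with Agrp (0.145), Npy (0.0138), Crh (-0.263), Trh (-0.150), Insr (0.0441) and Igf1r (0.182). Cyclic loess turned glycolysis (0.628), unfolded protein (0.732) and endothelial (0.837), and the restriction by row share feeding (0.819), endothelial (0.203) and red blood cell (0.832) lists.

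Leaving out single animals also turned directions. Log2 fold changes then ran from -0.923 to 0.367 for Agrp, -0.0331 to 0.153 for Bdnf, -0.137 to 0.360 for Crh, -0.278 to 0.0329 for Gfap, -0.326 to 0.0121 for Lepr, -0.407 to 0.149 for Npy and -0.968 to 0.0563 for Pomc. Adjusted p ran from 0.233 to 0.908 for endothelial, 0.172 to 0.955 for ependymal, 0.483 to 0.981 for feeding, 0.0959 to 0.955 for glucocorticoid, 0.0796 to 0.867 for red blood cell, 0.441 to 0.986 for striatum, 0.0508 to 0.885 for tanycyte and 0.00218 to 0.636 for thalamus lists, from 0.0317 to 0.984 for coverage per FPKM unit and from 0.246 to 0.984 for the mitochondrial share.

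The animal numbers were not taken to pair the groups, because the rule asks every correlation of deviations to be over 0.1. For numbers 1, 2, 3 and 5 they were 0.087, 0.49, 0.12 and 0.47, so 3 of 4 were over it, and 2 of 4 correlated best with their own number. Whether a number marks a shared batch is not known. With the number as a block 0 genes passed (smallest adjusted p 0.0995) and 11 lists were called, among them choroid plexus (0.0247), glucocorticoid (0.0239) and thalamus (0.0370), while ependymal and striatum lists turned (both 0.934). The glycolysis call ended under this block (0.104). Depth limits cannot be given without counts.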

Other observations

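The test on short RNAs had its bounds set before its value was seen; the other tests in this part were chosen after. The 3 long noncoding RNAs named here, chosen after their values were seen, had lower values in TBI. Long noncoding RNAs were not tested as a class. Snhg11 was 42.7 ± 13.1 in sham and 19.4 ± 2.91 in TBI, RGD1566401, whose synonym in the GRCr8 table is Meg3, was 128 ± 41.2 and 60.3 ± 6.88, and Miat was 15.2 ± 3.48 and 9.74 ± 0.360 (SD, n = 5 each). The groups did not overlap for any of these 3 RNAs, and limma adjusted p was 0.208, 0.222 and 0.224. Snrnp70, a protein of the U1 spliceosomal particle and also chosen after, was 68.9 ± 16.1 and 41.4 ± 3.89 (adjusted p = 0.237).

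The means of 3 abundant short RNAs, chosen after their values were seen, were higher in TBI, and none passed the threshold. Rmrp, the RNA of a mitochondrial and nucleolar RNase, was 23736 ± 1539 in sham and 31624 ± 4636 in TBI, Bc1 had a log2 fold change of 0.59, and LOC102723236, which stood at 2 places, one of 0.84. The groups overlapped for Bc1 and Rmrp. A rise of short annotated genes in general ran against the data. Of 74 other annotated genes of at most 400 bp, 17 had higher and 57 lower values. Their median log2 fold change was -0.1624 (bootstrap interval over genes, not animals, -0.34 to -0.09). These genes were not matched on abundance to the 3 RNAs, and fold change ran with abundance. Better recovery of abundant short RNAs is therefore not decided. Less background in TBI libraries raising every annotated gene alike cannot set these values, since the size factors remove a common shift. After scaling the median log2 fold change of all tested genes was 0.008, against 0.59 for Bc1 and 0.84 for LOC102723236. Less background acting unevenly on genes stays open. As deposited the median of all tested genes was -0.07095, but the assembled part of that column has a fixed total. A rise of abundant RNAs then lowers the other genes, so this value decides nothing. Injury itself and a difference in library preparation stay open as untested.

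Pituitary hormone genes differed between animals of both groups. Gh1 and Prl reached at most 0.2905% of Cga in the 4 animals with Cga above 98. This argues against anterior pituitary tissue rich in Gh1 and Prl. Anterior pituitary tissue with little of both is not addressed by this test. Tshb was 287, 203 and 41.8 in sham replicates 1, 3 and 5, 177 in TBI replicate 5, and at most 2.46 elsewhere. How far the dissection reached is a candidate explanation. Thalamus and tanycyte scores ran opposite over 10 animals (Pearson r = -0.7158, permutation p = 0.0221; Spearman rho = -0.48, permutation p = 0.165). Without the 2 animals farthest in thalamus score r was 0.34 (permutation p = 0.401), so that relation rests on sham replicate 6 and TBI replicate 4. It uses no pituitary gene, so it does not bear directly on Cga. The 4 animals with Cga above 98 had the highest tanycyte scores, 0.166 to 0.537, against at most 0.155 in the others. This was seen in the values and not tested. Injury cannot have set sham animals apart, where every lane of replicates 1, 3 and 5 lay at least 28.04 times above every lane of replicates 2 and 6. Between TBI animals, where replicate 5 alone was high, dissection and injury cannot be told apart with 5 animals per group (log2 Cga between groups, exact permutation p = 0.4127), and records of the dissection were not used here.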
